A study of Macaca mulatta with 161 samples.

How the data were processed

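Single inner cells of rhesus monkey blastocysts were measured by RNA sequencing, 1 library per cell. Per the labels' protocols, oocytes of hormone-stimulated females were fertilised and cultured, the outer cells of each blastocyst were stained with the membrane dye PKH26, and disaggregated cells without fluorescence were taken as inner cells. Their cDNA was amplified by PCR and sequenced as 150-bp paired reads. The submitters' processing notes name FastQC, TopHat2 2.1.0, HTSeq and DESeq2, with no role or order. The genome build and the annotation are not given in the sources used here.

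The values analysed are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of a cell), which the authors deposited as 1 table of 16049 gene symbols and 161 cells. All columns matched a cell's title. The table has no values in count units, but its low values come in steps. Comparing these steps between cells gave the value of 1 read for 13834 of the 13857 genes with a value above 0 in at least 2 cells, every value being whole within a relative tolerance of 2e-06 or an absolute tolerance of 1e-05. The recovered reads had a median of 11.0 M (mega) per cell (range 2.89 to 18.6 M), and these genes made up 78.2% to 97.1% of a cell's summed FPKM, so that they are a lower bound on depth. PCR reads carry no molecular identifiers. Intervals on shares of cells cover the counting error of cells only, and may be too narrow where cells share embryos.

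Cells were grouped by the stage in their labels. The labels name no embryo, animal or culture behind a cell, so each stage is 1 sample and cells are not replicates. No test between stages was made, and no p-value, standard error or count of changed genes is given. Each gene is described by the mean over cells of log2(FPKM + 1), the SD between cells, and the share of cells at FPKM of at least 1 with an exact Clopper-Pearson 95% interval. Differences are on the log2(FPKM + 1) scale, which understates the difference of low genes. The gene lists, the class markers and the rule for naming genes were fixed before the data were examined. Lists are described by the median difference of their members with mean FPKM of at least 1 (9781 genes of the table passed), with the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. This percentile describes these libraries and is not a test. Of 298 list genes, 31 have no row under their symbol and were not analysed here, among them GATA6, KLF2, DPPA4, TEAD3, SUSD2, ZIC5 and all members of the Y-linked list.

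Cell classes were found within each stage from the 1000 most variable genes, leaving out every list gene, by 10 principal components, Ward clustering and the k of 2 to 4 with the highest silhouette. The rule for naming a cluster was set after seeing the clusters. A cluster was named when it had at least 5 cells and at least 3 markers of 1 class at least 1 log2 unit above the other cells of its stage, more than of any other class, and the highest mean level of that class. It also needed at least 3 of these markers at FPKM of at least 1 in 50% of its cells, and no other class with more markers among its 10 most raised genes. In cells simulated without classes this rule still named 11 of 52 cells. A condition was therefore added after that result, that the silhouette exceed the highest of 20 versions with each gene shuffled over the cells. It left 0 of 52 such cells named and changed no class in the real cells. "EPI-like" stands for epiblast, "PE-like" for primitive endoderm and "TE-like" for trophectoderm. Cells were picked singly, and no doublet caller was run. Because no early or middle cluster was named, the planned comparison of hatching with early EPI-like cells was made with the late stage, the nearest that has them.

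Named genes follow a rule of size. For hatching minus early, it takes the 12 genes with the largest positive and the 12 with the largest negative difference among proper symbols at FPKM of at least 1 in 50% of cells of the higher stage, whose median cell moves the same way. It takes 10 and 10 genes for EPI-like cells, 5 and 5 for each neighbouring step, up to 4 members of a reported list among those with the largest absolute difference, and 19 fixed genes, of which 18 have a row. Other genes that are named were chosen after their values were seen.

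Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9. Every cell was also reduced to 2.5 M of its recovered reads to compare gene numbers. On simulated cells for hatching minus early, over 16049 genes, the planted sign was recovered for 98 of 100 genes moved by 1 log2 unit and for 100 of 100 moved by 2. Of 100 unchanged lists, 2 lay outside the middle 95% of random lists, and a list of raised genes lay at percentile 100. These simulated cells were drawn gene by gene from the early cells, which removes links between genes and between cells. They therefore cannot show how often lists of real cells lie outside without a stage difference. On simulated FPKM, a step was found for 12648 of 12715 genes, with every count exact. The simulated values were not rounded, so they cannot show how well steps are found in values written to limited decimals. In simulated late cells with planted classes, 52 of 52 cells got their class. These classes were planted far apart and each gene was drawn on its own. The result therefore cannot show how real cells between classes are named. The alternatives were other pseudocounts, levels, scalings, filters, detection limits and clusterings, and leaving out cells. Splits by the number in the cells' titles were added after seeing the data: the early boundary came from the clusters, the others from the X-linked share of expression. Titles of 7 cells (2 middle, 5 late) start with HS, whose meaning is not given in the sources used here. These cells were kept in their stage and left out as an alternative. The late number ranges 3 to 22 and 25 to 61 do not include them. The planned correlations of list scores across cells are not given, since cells of a stage may share embryos, which the labels do not name, and fall into separate clusters in the late and hatching stages. The size of many list medians depends on the pseudocount by more than 1.5-fold, while lists outside the middle 95% kept their sign under the alternatives unless stated. RefSeq genes of a rhesus assembly were used only to place 91.5% of the symbols on a chromosome.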

Results

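The data are 161 single inner cells from 4 stages of cultured rhesus monkey blastocysts, and the series asks about naive and primed pluripotency before implantation. The early blastocyst (about embryonic day 5, small cavity) has 44 cells, the middle blastocyst (about day 5.5) 39, the late blastocyst (about day 6, fully expanded) 52 and the hatching blastocyst (about day 7) 26. The median of recovered reads was 10.5 M per cell in the early stage, 11.9 M in the middle, 10.3 M in the late and 10.8 M in the hatching stage. A median of 7020, 7094, 6962 and 6714 genes reached an FPKM of 1 in these stages. With every cell reduced to 2.5 M reads, the expected number of genes with a read was 7776, 8003, 7821 and 7787. No 2 cells had identical values. Each stage is 1 sample, since no embryo is named, and all values below are descriptions of these cells without a replicate check.

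From the early to the hatching stage, naive pluripotency genes were lower and primed pluripotency genes higher. The naive list (genes of the pre-implantation epiblast state) had a median difference of -0.88, at percentile 0.5 of random lists, with 10 of 16 members lower. ESRRB differed by -5.21, KLF4 by -4.03, ARGFX by -3.29 and TBX3 by -2.77. The primed list (genes of the post-implantation epiblast state) had a median of 1.58 at percentile 100, with 17 of 19 members higher, among them ZIC2 at 3.82 and LIN28B at 2.85. OTX2, a homeobox factor on the primed list, went the other way at -3.52. The median over all 9781 genes was -0.12 in this contrast, and -0.00 with median-of-ratios scaling. The primed median depended on the setting, from 0.81 at a pseudocount of 10 to 2.68 at a pseudocount of 0.1.

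Members of the naive list differed from each other. DPPA3 had a mean log2 level of 11.02 (SD 0.92, n = 44 cells) in early and 10.41 (SD 0.70, n = 26 cells) in hatching cells, and DPPA5 had 9.70 (SD 1.33) and 9.85 (SD 2.95). KLF17 was found in 34.1% of early cells (95% interval 20.5% to 49.9%) and 46.2% of hatching cells (26.6% to 66.6%). TFCP2L1 differed by -1.73. ZIC2 reached an FPKM of 1 in 1 of 44 early cells and in 22 of 26 hatching cells. KLF4, a zinc-finger factor, was found in all 44 early cells and in 53.8% of hatching cells (33.4% to 73.4%).

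Core pluripotency genes had a median difference of 0.99 (percentile 100) from early to hatching. POU5F1 was detected in every cell of every stage, at a mean of 9.86 (SD 0.60) in early and 9.47 (SD 2.46) in hatching cells. NANOG had 7.30 (SD 0.99) and 7.27 (SD 3.21), and SOX2 1.87 (SD 1.80) and 3.18 (SD 2.15). GDF3 differed by 3.44, LIN28A by 1.75 and L1TD1 by -1.29. By the cell classes described below, the median was 1.87 for hatching EPI-like minus early and -2.12 for hatching PE-like minus early, but 7 of the 11 members are markers that named the classes. The 4 others had -0.49 (percentile 5.76) for late and -2.17 (percentile 3.19) for hatching PE-like minus EPI-like cells, both inside the middle 95%, and -2.41 (percentile 1.52) for the hatching cells numbered 1 to 18. The whole core list had -0.26 for hatching minus early with the 12 hatching cells numbered 1 to 18 alone, of which 7 were PE-like.

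By the rule of size, the genes most above early levels in hatching cells were LGALS1 (a galectin) at 8.75, KRT19 (a keratin on the TE marker list) at 6.78, SPARC (a matrix glycoprotein) at 6.26 and FXYD5 at 5.92. They were followed by IGFBP4, PTPLA, SP8, PHGDH (serine synthesis), FGF13, SERPINH1, WNT5B and IGFBP2, at 4.77 to 5.11. Several of these rest on 1 of the classes described below, such as IGFBP4 with hatching means of 6.86 in EPI-like and 0.46 in PE-like cells, FGF13 with 6.58 and 0.41, IGFBP2 with 9.23 and 1.59, and FXYD5 with 7.70 and 1.55. SPARC had 5.51 and 9.79, both above its early mean of 0.40. LGALS1 had a mean of 1.83 (SD 2.01) in early and 10.58 (SD 1.00) in hatching cells. The genes most below early levels were CLDN4 (a tight-junction claudin) at -8.28, SPIC at -6.62, AQP3 (a water and glycerol channel) at -6.15 and TMEM176B at -6.09. ATP6V0D2, DPRX, COX7B2, ASAP2, ESRRB, M1AP, ITGB7 and FOLR1 were at -6.05 to -4.90. CLDN4 had a mean of 10.00 (SD 1.11) in early and 1.72 (SD 2.74) in hatching cells.

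Most of these differences lay between the middle and hatching stages. From early to middle, the naive and primed lists had medians of -0.05 and -0.00, at percentiles 34.6 and 25.3, with a median over all genes of 0.08 that was 0.22 after rescaling every cell to the same sum. The rule took FKBP6, UCP2, TYROBP, MYC and NME4 (2.21 to 2.92) as higher in middle cells, and TMEM119, NDUFA1, CFC1, COX7B2 and TST (-4.48 to -3.12) as lower. Glycolysis genes had a median of 0.59 in that step (percentile 100), with TPI1 at 1.17 and SLC2A1 at 1.11, but the list also differed within the early stage, by 0.32 (percentile 99.2) for numbers 29 to 48 minus 1 to 28. From middle to late, the naive list had -0.66 (percentile 0.03) and the primed list 0.70 (percentile 100). SPARC, LGALS1, KRT19, MGST1 and NID2 were higher (3.53 to 3.97) and CLDN4, CLDN3, NDRG2, AQP3 and TMEM176B lower (-5.32 to -4.37). From late to hatching, the primed list had 0.88 (percentile 100) and the naive list -0.16 (percentile 64.1). LGALS1, IGFBP4, CYBA, PTPLA and PHGDH were higher by 4.41 to 5.04, and MT1B, GAST, CKMT1B, MT1G and the X-linked MSN lower at -5.63 to -3.71.

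The series title speaks of naive and primed states, and the score of each cell, its mean naive level minus its mean primed level, describes them jointly. The score was 3.61 (SD 0.36) in early, 3.51 (SD 0.52) in middle, 2.29 (SD 0.86) in late and 1.24 (SD 0.69) in hatching cells. The late and hatching values pool the cell classes described below. By class, the score was 2.69 (SD 0.70) in late and 1.50 (SD 0.47) in hatching EPI-like cells. It was 1.94 (SD 0.85) in late and 0.51 (SD 0.69) in hatching PE-like cells. Its zero is set by which genes are listed, so only differences between cells are read from it. The interquartile range was 3.31 to 3.85 in early and 0.82 to 1.74 in hatching cells.

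Epiblast and primitive endoderm classes could be named in the late and hatching stages. The late cells formed 24 EPI-like cells (46.2%, 95% interval 32.2% to 60.5%) and 28 PE-like cells (53.8%, 39.5% to 67.8%). The hatching cells formed 19 EPI-like cells (73.1%, 52.2% to 88.4%) and 7 PE-like cells (26.9%, 11.6% to 47.8%). All 7 hatching PE-like cells have title numbers 1 to 18, and the labels do not say from how many embryos they came. With 5 principal components these 7 cells stayed unnamed. No early or middle cluster was named, and groups of fewer than 5 cells could not have been. Some larger clusters had raised markers of 1 class but failed because the mean level of the EPI markers was higher. The early cluster of 19 cells and the middle cluster of 26 had 5 TE markers raised each. The middle cluster of 6 cells had 3 PE markers raised. Each of these clusters also had 1 EPI marker raised. By marker score alone, which gives every cell a class, 42 early, 33 middle and 28 late cells were EPI-like, 0, 2 and 23 PE-like, and 2, 4 and 1 TE-like. The early cells formed clusters of 19, 24 and 1 cells, and the middle cells of 26, 5, 6 and 2. The middle cluster of 26 cells holds title numbers 1 to 28, and those of 5 and 6 cells hold 32 to 45 and 33 to 55. Middle cells numbered 32 to 55 minus 3 to 29 had TE markers at -0.67 (percentile 0.23), oocyte transcripts at -1.14 (percentile 1.06) and p53 response genes at 0.55 (percentile 99.7). What sets these ranges apart was not tested. No cluster was named TE-like in any stage. With all stages clustered together, 13 late cells joined the early and middle cells and the PE-like share of the late stage was 30.8%.

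**Figure D1:**
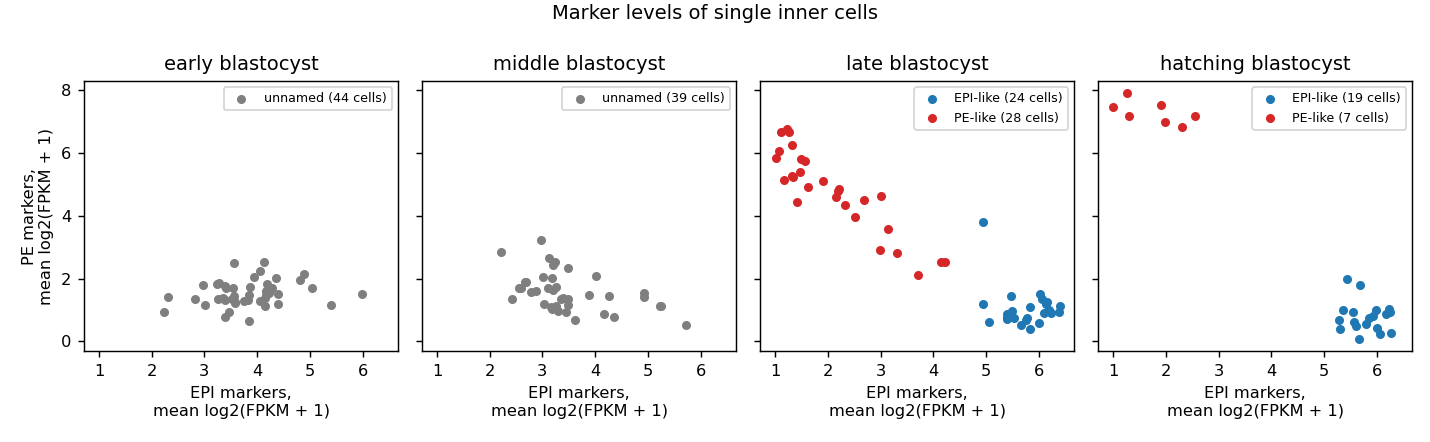
Mean log2(FPKM + 1) of the epiblast (EPI) markers on the horizontal axis and of the primitive endoderm (PE) markers on the vertical axis, 1 point per cell and 1 panel per stage, coloured by class. The 7 hatching PE-like cells lie apart from the EPI-like cells. The late cells run from one class to the other, some PE-like cells having higher EPI than PE marker means, and the early and middle cells are grey.

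Markers of several lineages were found in the same early cells. CDX2, a trophectoderm factor, was detected together with NANOG in 43 of 44 early cells (97.7%, 88.0% to 99.9%) and in 37 of 39 middle cells (94.9%, 82.7% to 99.4%). In late cells it was 10 of 24 EPI-like (41.7%, 22.1% to 63.4%) and 17 of 28 PE-like cells (60.7%, 40.6% to 78.5%), and in hatching cells 8 of 19 (42.1%, 20.3% to 66.5%) and 5 of 7 (71.4%, 29.04% to 96.3%). PDGFRA, a receptor of the primitive endoderm, was detected with NANOG in 31 of 44 early cells (70.5%, 54.8% to 83.2%), 4 of 24 late EPI-like cells (16.7%, 4.74% to 37.4%) and 0 of 19 hatching EPI-like cells (up to 17.6%). In PE-like cells the pair was found in 22 of 28 late (78.6%, 59.05% to 91.7%) and 7 of 7 hatching cells (100%, 59.04% to 100%). Detection needs only an FPKM of 1, and NANOG had a low mean log2 level of 2.12 in hatching PE-like cells. GATA4 and SOX17 are endoderm transcription factors. GATA4 was detected with NANOG in 7 of 44 early (15.9%, 6.64% to 30.1%), 5 of 24 late EPI-like (20.8%, 7.13% to 42.2%) and 4 of 19 hatching EPI-like cells (21.1%, 6.05% to 45.6%), and SOX17 in 6 (13.6%, 5.17% to 27.4%), 2 (8.33%, 1.03% to 26.997%) and 2 (10.5%, 1.30% to 33.1%). In middle cells GATA4 was found with NANOG in 2 of 39 (5.13%, 0.63% to 17.3%) and SOX17 in 10 of 39 (25.6%, 13.04% to 42.1%). Both pairs were more frequent in PE-like cells. Each was found in 21 of 28 late PE-like cells (interval 55.1% to 89.3%) and in 7 of 7 hatching PE-like cells (59.04% to 100%). These pairs were chosen after their values were seen.

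In EPI-like cells, hatching minus late, the primed list was higher with a median of 0.83 (percentile 100) and 14 of 19 members higher. CD24 differed by 4.80, LIN28B and SFRP2 by 2.34 each, and ZIC2 had a mean of 1.17 in late and 4.37 in hatching EPI-like cells. The naive list had -0.37, at percentile 2.97 and so just inside the middle 95% of random lists, with NLRP7 at -1.64 and KLF4 at -1.54 against ZFP42 at 1.94. The core list had 0.40 (percentile 99.1), led by UTF1 at 2.37. NANOG had a mean of 9.14 (SD 0.44) in late and 9.17 (SD 0.35) in hatching EPI-like cells, and POU5F1 10.33 (SD 0.31) and 10.90 (SD 0.23). DNMT3B, a de novo DNA methyltransferase, differed by 1.36, FGF4 by -0.84, OTX2 by -0.99 and NODAL by -0.10. With the 5 hatching EPI-like cells numbered 1 to 18 alone, the primed median was 0.37 and the naive median -0.21. The higher-numbered hatching EPI-like cells minus these 5 had a naive median of -0.33 (percentile 0.70) and a primed median of 0.0012. A naive difference similar in size to the -0.37 between stages thus also lay between number ranges of the hatching EPI-like cells. With late cells numbered 25 to 61 alone, the naive median was -0.78.

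By the rule of size, IGFBP4 (5.77), NPY (5.23), PHGDH (4.95), CD24 (4.80), PTPLA (4.70), CYBA (4.59) and LGALS1 (4.03) were the highest in hatching against late EPI-like cells, followed by ITM2C, IGFBP3 and UBD at 3.82 to 3.93. The metallothioneins MT1B (-6.19) and MT1G (-4.52) were lowest, followed by GAST (-4.48), CTSL2 (-4.26), CKMT1B (-4.15), IL1R2, PLLP and SPIC, and the X-linked EBP and MAGED2 at -3.53 and -3.52. Metallothionein genes are near-identical copies between which reads can be split. Some of these genes also set number ranges apart within the early stage. CD24 was among the 10 most raised genes of the early cluster numbered 29 to 48. GAST and the metallothioneins MT1F and MT1H were among those of the early cluster numbered 1 to 28. Against all early cells, hatching EPI-like cells had a naive median of -1.08 (percentile 0.01) and a primed median of 1.75 (percentile 100), or -0.71 for the naive list with the cells numbered 1 to 18 and 1.04 for the primed list at a pseudocount of 10.

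**Figure D2:**
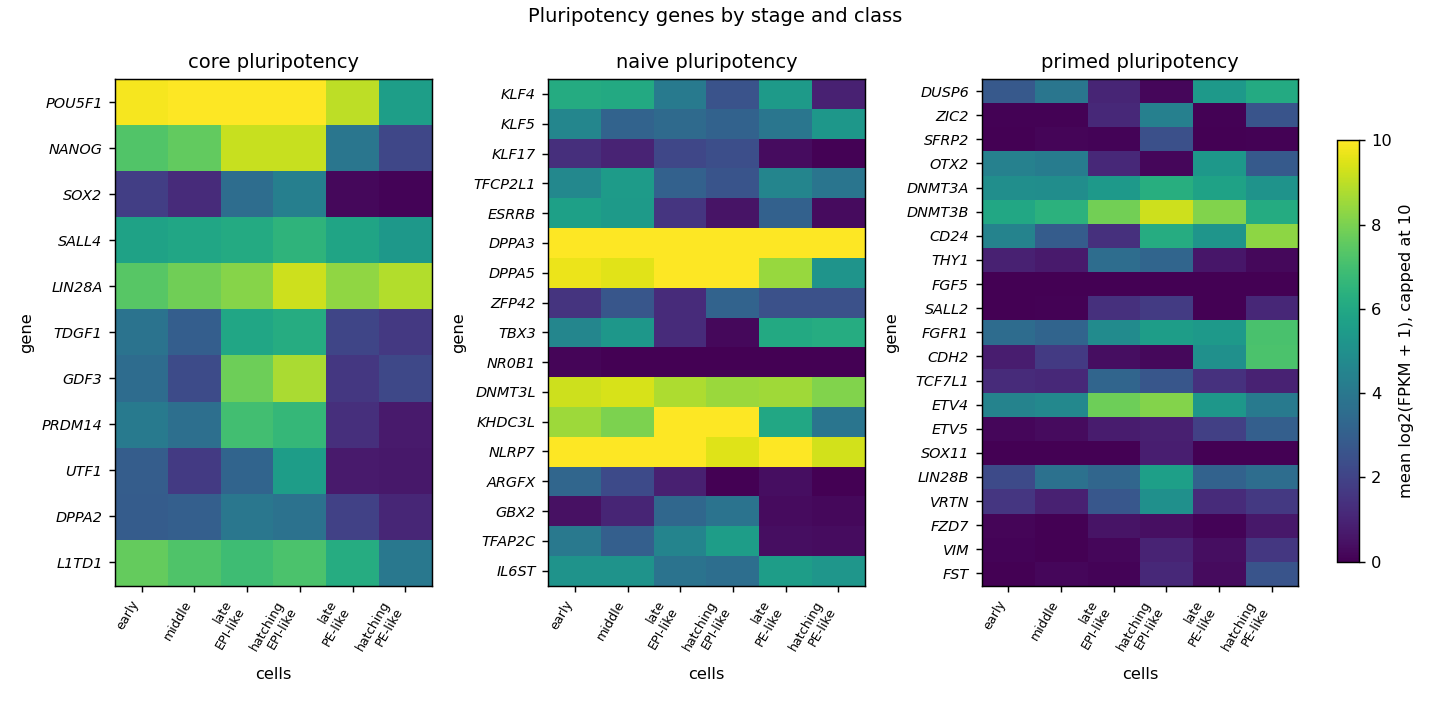
Mean log2(FPKM + 1), as colour capped at 10, of core, naive and primed pluripotency genes (rows) in early cells, middle cells and the EPI-like and PE-like cells of the late and hatching stages (columns). ESRRB goes from 5.68 in early cells to 0.53 in hatching EPI-like cells, and ZIC2 from 0.06 to 4.37.

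Primitive endoderm and epiblast were compared within the stages that hold both, with the markers that named the classes left out of every list. In late cells, basement membrane genes were higher in PE-like cells with a median of 3.10 (percentile 100, 7 of 7 genes), led by COL4A2 at 3.83 and NID1 at 3.69. LIF and JAK-STAT genes had 1.09 (percentile 99.99), with IL6R at 4.55, IL6ST at 1.78 and LIFR at 1.30. FGF and ERK genes had 0.56 (percentile 99.6), with DUSP6 at 4.32 and FGFR4 at 2.58. BMP genes had 0.54 (percentile 98.3), and lipoprotein and endodermal secretion genes 0.78 (percentile 99.8). The naive and primed lists had -0.14 and 0.19, at percentiles 26.2 and 90.9, with members on both sides, and the naive median was 0.17 when cells were summarised by their median. KHDC3L (-5.84), TFAP2C (-4.12) and DPPA5 (-3.13) were lower in PE-like cells, while TBX3 (4.87), OTX2 (4.15), TFCP2L1 (1.43) and KLF4 (1.34) were higher. With classes by marker score, the naive and primed medians were -0.23 and 0.27. Only 16 of the 28 late PE-like cells stayed PE-like with all stages clustered together. How far the remaining cells shape the naive median and members such as KLF4 was not tested. Among late cells numbered 3 to 22 and 25 to 61, the basement membrane medians were 3.22 and 3.17 and the LIF medians 1.04 and 0.93, while the primed medians were 0.35 and -0.20. Among numbers 3 to 22, FGF (0.35, percentile 92.5), BMP (0.46, percentile 94.5) and lipoprotein genes (0.45, percentile 95.3) lay inside the middle 95%, and over 9747 genes the differences in these number ranges had a correlation of 0.60.

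In the hatching stage, basement membrane genes were higher in PE-like cells by a median of 5.15 and lipoprotein and endodermal secretion genes by 4.37, both at percentile 100. TTR (transthyretin) differed by 5.98 and MTTP by 5.91. LIF and JAK-STAT genes had 1.41 (percentile 99.96) and BMP genes 1.03 (percentile 99.4). Mitotic genes were lower in all 12 members, with a median of -3.92 (percentile 0), TOP2A at -5.46 and CCNB1 at -4.95. The hatching PE-like cells had fewer genes at FPKM of 1, a median of 5680 against 6940, and fewer recovered reads, 8.39 against 12.4 M. The 5 EPI-like cells that share their numbers 1 to 18 had 6539 genes and 8.37 M reads. APOA1 alone made up a median of 6.26% of the FPKM of the PE-like cells, and the median of all genes was -0.45, or -0.16 with median-of-ratios scaling. DNA methylation genes had -2.07 (percentile 0.54), led by ZFP57 at -5.21. Against the 5 EPI-like cells that share the numbers 1 to 18, mitotic genes had -2.73 (percentile 0), BMP genes 1.69 (percentile 99.8) and DNA methylation genes -1.63 (percentile 2.58, inside the middle 95%). The naive and primed lists had -0.35 and -0.62, at percentiles 81.8 and 19.1, and the primed median was 0.49 with the log2 of the mean FPKM.

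Between hatching and late PE-like cells, the PE markers had a median of 2.69 (percentile 100), with RSPO3 at 5.21 and BMP2 at 5.12. BMP genes had 2.51, basement membrane genes 2.75 and lipoprotein genes 3.74, all at percentile 100. POU5F1 had a mean of 9.02 (SD 0.66) in late and 5.60 (SD 1.01) in hatching PE-like cells, and NANOG 3.91 (SD 2.99) and 2.12 (SD 0.56). With only the 16 late cells that were PE-like when all stages were clustered together, the late means were 8.59 (SD 0.51) for POU5F1 and 1.93 (SD 1.37) for NANOG, so that NANOG was not lower in hatching cells. The medians were then 1.93 for PE markers, 2.29 for BMP, 1.80 for basement membrane and 2.99 for lipoprotein genes. The median over all genes was -0.42, or -0.13 with median-of-ratios scaling.

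The other lists, hatching minus early over all cells, lay on both sides of 0. The EPI markers had 1.08 and the PE markers 1.96, at percentiles 99.99 and 100, and the TE markers -0.34 at percentile 11.1. KRT19, on the TE list, went the other way from its list median at 6.78. NODAL and activin genes had 1.17 (percentile 99.98), with NODAL at 4.14 and LEFTY1 at 2.83, but 0.45 (percentile 91.8) for hatching EPI-like minus early. FGF and ERK genes had 0.94 (percentile 99.98), BMP genes 1.40 (99.99), Hippo genes 0.79 (99.7, but -0.26 among genes with a mean FPKM of at least 5) and DNA methylation genes 0.81 (99.9), the last with DNMT3B at 2.42 and DNMT1 at 2.26. Basement membrane genes had 1.80 (99.99) and lipoprotein genes 1.34 (99.98). Oxidative phosphorylation genes had -0.85 (0.8), led by the X-linked NDUFA1 at -2.88. Stress and dissociation genes had -0.98 (0.15), all 12 being lower and FOS leading at -2.99. Lists inside the middle 95% were WNT at 0.32, LIF and JAK-STAT at -0.37, glycolysis at -0.24, mitotic cell cycle at -0.45, cleavage-stage genes at -0.26, p53 response at -0.56, and the 2 measured oocyte transcripts at 0.04. The PE marker, basement membrane and lipoprotein medians were -0.42, -0.26 and -0.46 with the hatching cells numbered 22 to 47 alone, none of which was PE-like. The EPI marker median was -0.48 with cells numbered 1 to 18 alone.

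**Figure D3:**
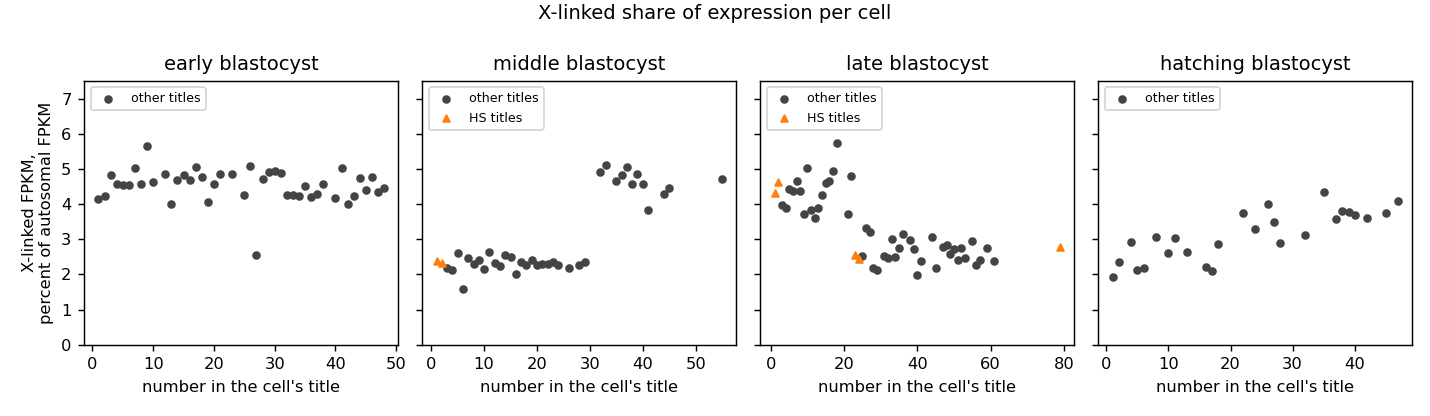
Summed FPKM of X-linked genes as a percent of that of autosomal genes (vertical axis) against the number in the cell's title (horizontal axis), 1 point per cell and 1 panel per stage, with triangles for cells titled HS. Middle cells numbered 32 to 55 lie at 3.83% to 5.11% and the other middle cells at 1.58% to 2.63%.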

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

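Settings that split cells by title number were chosen after seeing the data, as were naming classes by marker score and PE-like hatching minus late with all stages clustered together. No paired analysis was possible because the replicate numbers are in accession order and the results come from no test. Of 2809 values under alternatives, 2584 moved by less than the spread between cells (or, for shares, stayed within the interval), 213 moved by more, and 12 values of lists outside the middle 95% changed sign. The naive list stayed negative under every alternative for hatching minus early, for hatching EPI-like minus early and for EPI-like hatching minus late, and moved by less than the spread. For EPI-like hatching minus late, its median was -0.37. It ran from -0.78 with late cells numbered 25 to 61 to -0.21 with hatching cells numbered 1 to 18. Moving by less than the spread between single cells therefore says little about how stable this median is. The per-cell score was lower than in the earlier group by more than the SD between cells in all 3 contrasts under both alternatives. The primed list kept its sign in these contrasts, with sizes that depended on the setting. For hatching minus early it was 2.68 at a pseudocount of 0.1, 0.81 at 10, 2.58 with the log2 of the mean FPKM, 0.95 with the median over cells, 2.36 with a mean FPKM of at least 5, and 2.07 with hatching cells numbered 22 to 47. For hatching EPI-like minus early it was 2.45 at a pseudocount of 0.1, 1.04 at 10, 2.14 with FPKM rescaled to the same sum and 2.22 with a mean FPKM of at least 5. For EPI-like hatching minus late it was 0.37 with hatching cells numbered 1 to 18. For hatching PE-like minus EPI-like, where it lay inside the random range, it was -1.17 and -0.15 at pseudocounts of 0.1 and 10, 0.49 with the log2 of the mean FPKM and -1.42 with a mean FPKM of at least 5. The PE-like share of hatching cells was 0% with 5 principal components, which left those 7 cells unnamed, and that of late cells was 30.8% with all stages clustered together.

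Glycolysis in hatching PE-like minus EPI-like changed sign at a pseudocount of 10 (0.0084), with the log2 of the mean FPKM (0.11), with median-of-ratios scaling (0.18) and with a mean FPKM of at least 5 (0.0238). Hippo genes, hatching minus early, were at -0.26 with a mean FPKM of at least 5. With hatching cells numbered 1 to 18 alone, the EPI markers (-0.48) and core genes (-0.26) of hatching minus early, DNA methylation genes of EPI-like hatching minus late (-0.0227) and mitotic genes of hatching EPI-like minus early (-0.45) changed sign. With those numbered 22 to 47 alone, the PE markers (-0.42), basement membrane genes (-0.26) and lipoprotein genes (-0.46) of hatching minus early did, there being no PE-like cell among them. The EPI marker and core sign changes go with the 7 PE-like cells among numbers 1 to 18, since EPI-like cells numbered 22 to 47 differed from those numbered 1 to 18 by -0.02 and 0.02 in these lists. The PE marker, basement membrane and lipoprotein lists differed by -0.46, -0.27 and -0.22 between the same EPI-like cells, so that class is not the only difference there. The mitotic sign change goes with the number range, since EPI-like cells numbered 22 to 47 differed from those numbered 1 to 18 by 1.27 (percentile 100). What sets these ranges apart was not tested. For glycolysis, Hippo and DNA methylation genes the cause was not tested.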

Other observations

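All tests of explanations in this part were chosen only after the result was seen. Oocyte transcripts, listed to look for maternal remains, were not evenly spread in late cells: KHDC3L and OOEP were lower in PE-like than EPI-like cells, with differences of -5.84 and -2.70. KHDC3L is also on the naive list, so the 2 lists are not independent there. Genes of cleavage-stage genome activation had a median of -0.77 in the same comparison (percentile 1.67, but -0.59 at percentile 5.56 among late cells numbered 25 to 61), led by DPRX at -3.65, which was found in all 44 early cells. X-linked genes had a median of -1.17 for hatching minus early, against -0.22 for the median autosome, and this stage difference is mixed with the spread of X-linked shares between cells described next.

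X-linked genes made up different shares of expression in cells of the same stage. Over 219 X-linked and 6279 autosomal genes, X-linked FPKM was 1.58% to 2.63% of autosomal FPKM in 27 middle cells and 3.83% to 5.11% in the 12 middle cells numbered 32 to 55, and in late cells it was 3.59% to 5.74% for numbers 3 to 22 and 1.99% to 3.32% for numbers 25 to 61, boundaries that were drawn from this share. A few genes are argued against, since middle cells assigned by 109 or 110 of the X-linked genes differed by at least 0.84 log2 in the remaining ones, and depth as the whole cause, since no threshold on depth put more than 82.1% of the middle cells on the right side of the gap (69.2% with all cells on 1 side). The late EPI-like and PE-like cells differed by 0.82 and 0.74 log2 between these numbers, which the choice of boundaries makes necessary in sign and is no test. A different number of active X copies in different embryos and developmental age within a stage stay open as untested, and Y-linked genes and embryo labels were not analysed here.

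The early cells split into clusters of 19 cells with title numbers 29 to 48 and 24 with numbers 1 to 28, the remaining cell being number 9. The number ranges differ in depth, with a median relative depth of 1.27 for numbers 29 to 48 and 0.76 for numbers 1 to 28. Sequencing depth as the whole cause is argued against, since with every cell thinned to 2.5 M reads and clustered anew, 100% of the 44 cells lay in 1 of 4 clusters of mostly their own number range (56.8% with all cells in 1 cluster). Different embryos, libraries or collection days stay open as untested, and no biological explanation was tested. TE markers had a median of 0.60 (percentile 99.9) for the higher against the lower numbers.

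Mitotic genes were low in the 7 hatching PE-like cells. The list lay at percentile 0 of random lists matched on expression, so it was lower than lists of genes of similar level. That percentile is the observation already given above. It is therefore no separate test of a general loss of genes in less complex libraries. Without the 20 most abundant genes of these cells, the median difference to EPI-like cells stayed at -3.73. Against the 5 EPI-like cells also numbered 1 to 18 it was -2.73, and these were themselves below the EPI-like cells numbered 22 to 47, by a median of 1.27, so a trait of all cells with these numbers could account for part of the difference but not all. With 7 cells of unknown embryos, a pause in division may be one explanation and a few unhealthy or single-embryo cells another, and neither was tested.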
